A study of Homo sapiens with 12 samples.

How the data were processed

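Genomic DNA of 2 human cell lines was compared after X-ray exposure: GM12878, a lymphoblastoid line grown in suspension, and IMR90, primary lung fibroblasts grown attached. Per the labels' protocols, DNA was sheared, methylated fragments were captured with an antibody against methylated cytosine (methylated DNA immunoprecipitation, MeDIP), a share of the sheared DNA was kept as input, and both fractions went through whole-genome amplification before labelling. Each line was sampled once after sham exposure (0 Gy, 0 h), once at 24 h and once at 48 h after 2 Gy, once at 24 h and once at 48 h after 4 Gy, and once at 96 h after 4 fractions of 0.5 Gy. This gives 12 arrays in 12 groups, with 1 array per group and no replicates, so fitted standard errors pool the scatter between groups and each lone sham array is assumed to vary like the others.

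Each 2-colour Agilent array carried MeDIP DNA in one dye and input DNA in the other. The sample labels put MeDIP DNA in Cy3 and input in Cy5, except on 3 IMR90 arrays (4 Gy at 24 h, 4 Gy at 48 h and the fractionated dose), where the dyes were exchanged. The labelling protocol in the labels names GM12878 DNA as the reference in a general sentence, whereas each sample's own label names input of the same line, treatment and time; the sample labels were followed. Before any turning, the log ratios of the exchanged arrays correlated with those of the other arrays at r from -0.84 to -0.50 across probes, and the 9 remaining arrays correlated with each other at 0.62 or above, so the arrays bear out the labelled orientation.

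Per the file headers, the authors extracted the images with Feature Extraction 12.0.3.1 (the submitters' processing notes give version 12.0) and deposited spot intensity values: processed signals that are background-subtracted, spatially detrended and dye-normalised by a linear factor, with no intensity-dependent curve, and median spot and background intensity values. The headers place the probes on hg19. The deposited log10 ratio of the value table equals the scanner log10 ratio of Cy5 over Cy3 on every array except for rounding (its column medians ran from 0.000118 to 0.0457), so its log base, centring and direction are known, and it is not turned by sample.

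From the processed signals, the log2 ratio of MeDIP over input was computed per spot, turned so that positive values mean enrichment of methylated DNA, and centred on each array's autosomal median. Loess and quantile normalisation were left out, since most probes carry signal. Control spots were dropped (leaving 415056 spots of 411056 distinct probes), spots flagged as outliers in either channel were left out (0.032% to 0.0593% per array), and spots of one probe were averaged. Of the probes, 389120 lie on autosomes and entered the comparisons, and 316 had no chromosome position and were left out. X probes (20105) entered only an alternative, and Y probes (1515) were not used. The values are relative: a level above 0 is above that array's autosomal median, and a change of the whole genome would be removed by the centring.

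The planned unit was the gene. The files pair no probe with a gene and no annotation of hg19 was used here, so fixed windows of 100 kb with at least 8 probes took its place (21241 windows, chosen after the files were seen but before any comparison was fitted). No gene is named, and the planned gene lists, promoter, exon, intron and CpG classes and the CpG trend were not run. Windows of 1 Mb with at least 50 probes (2642 windows) gave the regional scale. The MeDIP level also depends on the local density of methylated CpGs, which could not be modelled without a genome sequence.

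Each window was tested with limma 3.58.1 (lmFit and eBayes, in R 4.3.3), with Benjamini-Hochberg adjustment over windows and a threshold of 0.05. The line difference, dose, time and fractionation were contrasts of a fit with the 6 treatment-and-time levels, cell line and dye orientation (4 residual degrees of freedom). Irradiation in both lines came from a fit with line, irradiated and dye (8 residual degrees of freedom), and irradiation in each line and its interaction with line from a fit with line by irradiated and dye (7 residual degrees of freedom). Because the dye term takes up the 3 exchanged arrays, the line difference rests on the 3 pairs of arrays that share an orientation, and the IMR90 irradiation contrast rests on its 2 arrays at 2 Gy. The contrast for irradiation in both lines also takes IMR90 only from its sham and these 2 arrays. Regional classes (22 autosomes and probes within 5 Mb of a chromosome end) were tested with an exact permutation of which array of each line is called sham (36 choices, two-sided), and line differences of classes with an exact sign-flip test over the 6 treatment pairs. Runs of neighbouring called windows were compared with 200 shuffles of the calls within chromosomes, and the shares called per class with 2000 rotations of the calls along the genome.

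The fits were tested on simulated windows with the real design and residual spread, 200 of them changed by known sizes. For irradiation in both lines the test recovered 98.0% of windows changed by 1 on the log2 scale, 38.0% at 0.5 and 0 of 50 at 0.25. Of the 130 calls in that comparison, 12 were false. For IMR90 alone the test recovered 62.0% at a size of 1, and for the interaction 8.0%. At 0.5 it recovered 22% for the line difference and 6% for GM12878 alone.

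Named windows follow a rule written before the data were examined, applied to windows in place of genes: the 10 largest differences each way past the threshold with the same sign in all 6 pairs for the line difference, and, where no window passed, the 3 each way with the lowest p, given as values that did not pass. Alternatives chosen before the data were examined were normexp background correction (offset 50, on median signals), loess within arrays, a common median absolute deviation, no dye term, only the 9 arrays with unexchanged dyes, only probes well above background on all arrays, the deposited log10 ratios, X included, at least 1 or at least 5 probes per window, slide as a random block, a trended robust variance prior, a treatment-and-time term in place of irradiated or the reverse, 100 kb in place of 1 Mb windows, and leaving out each array. Scan day as a block, scaling of the window means, probe-dense windows (20 probes or more) and probe-sparse windows (14 or fewer), and the run and rotation tests were added after seeing the data. The arrays lay on 7 slides scanned on 4 days. The lines shared no day: in GM12878 the 2 Gy arrays had a day of their own, and in IMR90 the sham and 2 Gy arrays shared a day and the 3 exchanged arrays another. Figures were drawn with matplotlib 3.10.9.

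The number of arrays limits the precision. The share of spots well above background was 91.6% to 99.7% in the MeDIP channel and 99.4% to 99.8% in the input channel.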

Results

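MeDIP over input profiles were obtained for 389120 autosomal probes in 12 arrays, 6 of GM12878 lymphoblastoid cells and 6 of IMR90 lung fibroblasts. Each line contributed 1 sham array, 4 arrays after a single dose of 2 or 4 Gy at 24 or 48 h, and 1 array at 96 h after 4 fractions of 0.5 Gy. The study asked whether X-rays change DNA methylation and whether some regions of the genome respond more than others. The median spot intensity ran from 160 to 792 in the MeDIP channel and from 338.5 to 658 in the input channel. Over 21241 windows of 100 kb, arrays of GM12878 correlated with each other at r from 0.93 to 0.99, arrays of IMR90 at 0.87 to 0.99, and arrays of different lines at 0.66 to 0.84. These correlations are across windows, which are not independent replicates. No group had a replicate, and nothing in the labels says that arrays of a line came from separate cultures, so the p-values below do not measure scatter between replicates. For line, dose, time and fractionation they measure how the difference between the lines scattered over treatments. For irradiated against sham they also measure the scatter between arrays of different treatments. All positions are hg19.

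Enrichment of methylated DNA followed the chromosomes in both lines. Chromosome 19 had the highest mean log2 ratio in GM12878 (0.69 ± 0.14, SD over 6 arrays) and in IMR90 (0.44 ± 0.26). Chromosomes 22, 17 and 16 came next, at 0.52 ± 0.12, 0.52 ± 0.09 and 0.44 ± 0.07 in GM12878 and at 0.41 ± 0.23, 0.33 ± 0.19 and 0.28 ± 0.17 in IMR90. Chromosome 4 had the lowest mean, -0.29 ± 0.08 in GM12878 and -0.27 ± 0.07 in IMR90. Probes within 5 Mb of a chromosome end stood at 0.39 ± 0.12 in GM12878 and 0.33 ± 0.21 in IMR90. Windows rich in probes lay above the array median (0.25 ± 0.05 in GM12878, 0.18 ± 0.12 in IMR90) and windows poor in probes below it (-0.36 ± 0.09 and -0.33 ± 0.10). None of the 23 chromosome and chromosome-end classes differed between the lines after adjustment in an exact sign-flip test, for which the 6 pairs allow no p below 0.0312.

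**Figure D1:**
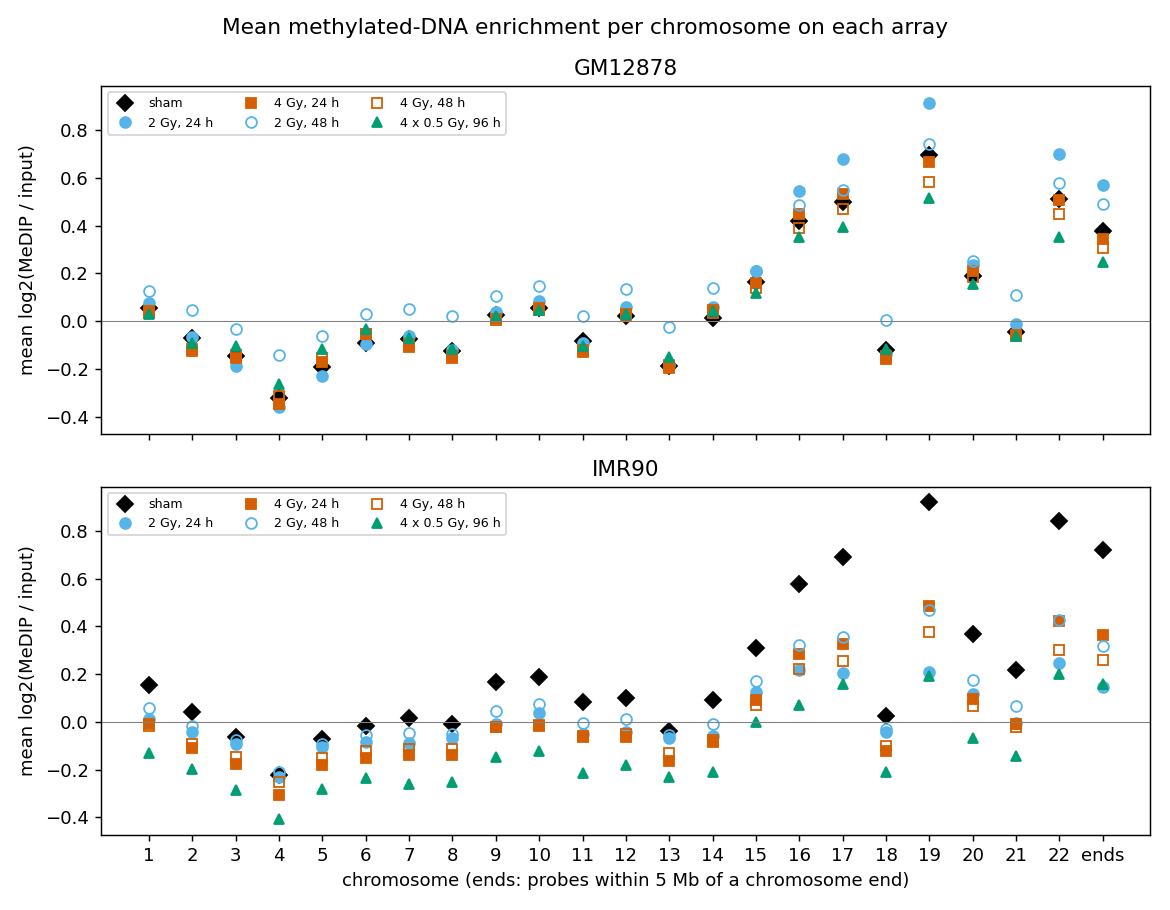
Mean log2(MeDIP / input) of the probes of each autosome and of probes within 5 Mb of chromosome ends, with 1 point per array (upper panel GM12878, lower panel IMR90; diamonds are sham arrays). Chromosome 19 is highest and chromosome 4 lowest by mean in both lines, and the IMR90 sham array lies above the 5 irradiated IMR90 arrays on chromosomes 16, 17, 19 and 22.

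The lines differed in windows on every autosome. Of 21241 autosomal windows, 7113 passed the threshold (33.5%), 4089 of them higher in IMR90 and 3024 lower, and 6716 of the 7113 had the same sign in all 6 treatment pairs. No scan day held both lines, so line and day cannot be told apart: with scan day as a random block no window passed, the windows named below included (287 at unadjusted p under 0.05, against 9736 without it). The sizes were then 0.68 and -0.48 in the median of higher and lower windows, close to 0.69 and -0.52 without the block, while the median SE was 0.48 in both against 0.12 and 0.13. The windows higher in IMR90 had a median log2 ratio of -0.46 in GM12878 and 0.23 in IMR90, a median fitted difference of 0.69 (1.61-fold). In GM12878, 81.5% of them lay below the array median, against 30.4% in IMR90. Windows lower in IMR90 had a median of 0.38 in GM12878 and -0.17 in IMR90, a fitted difference of -0.52 (1.43-fold lower). In 1 Mb windows, 732 of 2642 passed (27.7%), 497 higher and 235 lower in IMR90. The share called and the balance of higher and lower calls moved with the fit. Without the dye term 55.4% passed, 596 of these windows higher and most of them lower in IMR90. With only the 9 unexchanged arrays 12.7% passed, 280 of these windows higher and the rest lower.

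Windows called in the same direction formed longer runs of neighbours than shuffles of the calls gave, although many stood alone. Of 1673 higher and 1921 lower runs, 813 and 1270 held a single window. Higher windows formed 39 runs of 10 or more, which held 482 windows, whereas none of 200 shuffles within chromosomes gave a run of 10. The shuffles break any correlation between neighbours, so a smooth difference between arrays or scan days could exceed them too. The longest run, on chromosome 3 from 173400001 to 175600000, covered 22 windows (2.2 Mb). Its mean log2 ratio was -0.98 ± 0.19 in GM12878 and -0.01 ± 0.06 in IMR90 (SD over 6 arrays each), and the 6 pair differences ran from 0.68 to 1.27. Runs of 18 windows lay on chromosome 1 from 215800001 to 217600000 (-0.78 ± 0.17 in GM12878, 0.10 ± 0.08 in IMR90) and on chromosome 6 from 128000001 to 129800000 (-0.72 ± 0.18 and 0.04 ± 0.03). Runs lower in IMR90 were shorter, with a median of 1 window against 2 for higher ones, and only 1 reached 10 windows. This difference was not tested, and runs were formed from the main calls only. Runs of 9 windows lay on chromosome 7 from 125800001 to 126700000 (-0.41 ± 0.11 in GM12878, -1.38 ± 0.21 in IMR90) and on chromosome 16 from 23700001 to 24600000 (0.64 ± 0.06 and -0.27 ± 0.20). Windows higher in IMR90 were scarce near chromosome ends, where 9.5% were called against 19.3% over the genome (adjusted p = 0.046 over 46 rotation tests). Lower ones were also fewer there, 10.3% against 14.2%, which did not pass (adjusted p = 0.103). On chromosome 19 the share was 1.55% and missed the threshold (adjusted p = 0.0575).

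**Figure D2:**
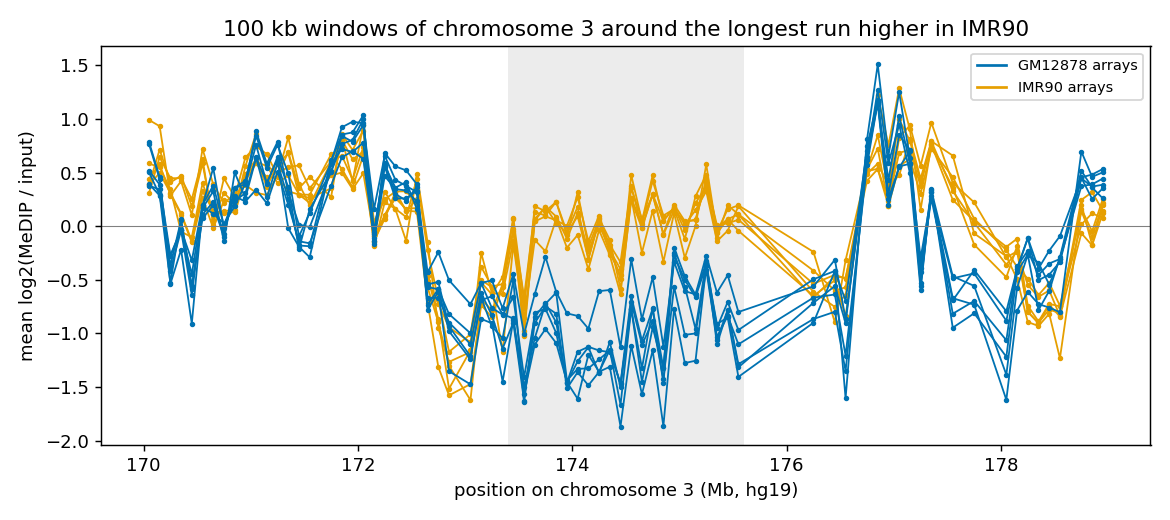
Mean log2(MeDIP / input) of 100 kb windows with at least 8 probes on chromosome 3, with 1 line per array (blue GM12878, orange IMR90) against position in Mb; the grey band marks the run from 173400001 to 175600000. Within the band the GM12878 arrays average -0.98 and the IMR90 arrays -0.01.

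The largest single-window rises in IMR90 clustered on the short arm of chromosome 5. The window from 8800001 to 8900000 was at -1.51 ± 0.31 in GM12878 and 0.18 ± 0.18 in IMR90 (fitted difference 1.76, SE 0.20, 3.39-fold, limma adjusted p = 0.000879), and 3 further windows from 9000001 to 9300000 had fitted differences of 1.51 to 1.63. The others of the 10 largest lay on chromosome 21 from 29500001 to 29600000 (1.62, SE 0.14), chromosome 4 from 126300001 to 126400000 (1.54, SE 0.16), chromosome 8 from 16100001 to 16200000 (1.53, SE 0.16), chromosome 15 from 96900001 to 97000000 (1.53, SE 0.15), chromosome 16 from 83200001 to 83300000 (1.49, SE 0.13) and chromosome 6 from 22500001 to 22600000 (1.49, SE 0.16). Their adjusted p lay between 0.000839 and 0.000879, and all 10 were higher in IMR90 in 6 of 6 pairs; with scan day as a random block neither these nor the falls below passed.

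The largest falls included 6 windows of chromosome 14 between 106400001 and 107000000, with fitted differences from -1.82 to -1.47, and the window of chromosome 2 from 89200001 to 89300000 (-1.86, SE 0.26, limma adjusted p = 0.00137). GM12878 arrays scattered widely there: the chromosome 2 window was at 0.42 ± 0.79 in GM12878 and -1.10 ± 0.25 in IMR90. The GM12878 input signal was also lower than that of IMR90 in these windows, by a median of -1.95 on the log2 scale over the 11 windows of the chromosome 14 run and the chromosome 2 window, so their ratios rest on little GM12878 DNA. The other 3 of the 10 lay on chromosome 12 from 103700001 to 103800000 (0.05 ± 0.14 in GM12878, -1.62 ± 0.24 in IMR90, fitted difference -1.58, SE 0.13), chromosome 10 from 26800001 to 26900000 (0.70 ± 0.16 and -0.83 ± 0.15, -1.57, SE 0.14) and chromosome 4 from 36000001 to 36100000 (0.57 ± 0.10 and -1.07 ± 0.22, -1.49, SE 0.13), each with adjusted p = 0.000839 and the same sign in 6 of 6 pairs.

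**Figure D3:**
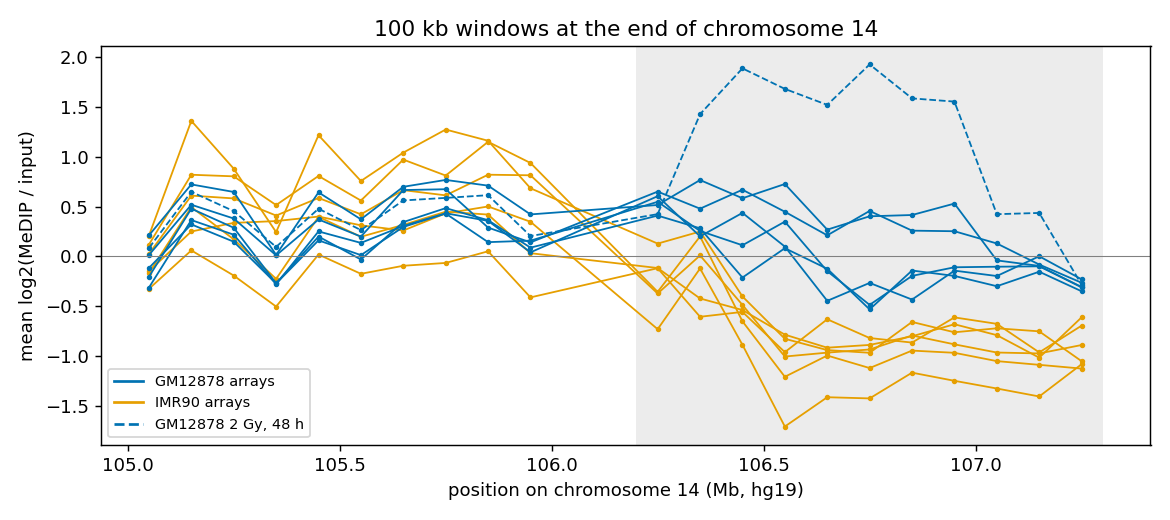
Mean log2(MeDIP / input) of 100 kb windows with at least 8 probes at the end of chromosome 14, with 1 line per array (blue GM12878, orange IMR90; dashed, GM12878 at 48 h after 2 Gy) against position in Mb; the grey band marks the run from 106200001 to 107300000. The dashed array reaches 1.93 in the window from 106700001, where the other GM12878 arrays average -0.08 and the IMR90 arrays -1.03.

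Apart from scan day, the count for the line difference depended on dye, scaling and single arrays. Without the dye term 12252 windows passed, with window means scaled to a common spread 10720, with only the 9 unexchanged arrays 4091, and without either array at 48 h after 2 Gy 3999. The share of called windows that were higher in IMR90 was 57.5%, against 39.3% without the dye term, 69.5% with 9 arrays, 41.9% without either sham array and 79.5% without either array at 48 h after 2 Gy.

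After irradiation, no window differed from sham in both lines together at limma adjusted p 0.05 (lowest 0.606), and 1681 of 21241 did at unadjusted p under 0.05, 399 of them higher and the rest lower. Because of the dye term, IMR90 enters this difference only through its sham and its 2 arrays at 2 Gy. Without the dye term, where all irradiated IMR90 arrays enter, no window passed either. Neighbouring windows were correlated (r = 0.64 for the differences of this fit), so chance can give shares far from 5%. This holds for the comparisons below too, which use the same windows. The 1681 were 7.91% of the windows, above the 5% that chance gives on average, but that count rested on single arrays. It was 594 without IMR90 at 24 h after 2 Gy and 1092 without IMR90 at 48 h after 2 Gy. It was 3579 without GM12878 at 24 h after 2 Gy. Without the sham of 1 line, this fit rests on the other line alone and gives that line's count, stated below. The median half-width of the 95% confidence interval of a window was 0.27 on the log2 scale. The 3 rises with the lowest p, none of which passed, lay on chromosome 7 from 17400001 to 17500000 (fitted difference 0.51, SE 0.11), chromosome 4 from 130000001 to 130100000 (0.36, SE 0.08) and chromosome 5 from 36500001 to 36600000 (0.41, SE 0.10). The 3 falls lay on chromosome 10 from 124000001 to 124100000 (-0.37, SE 0.09), chromosome 9 from 124400001 to 124500000 (-0.39, SE 0.10) and chromosome 7 from 55600001 to 55700000 (-0.39, SE 0.10). No window of 1 Mb passed either, with 72 of 2642 at unadjusted p under 0.05 (5 in GM12878 alone and 726 in IMR90 alone). No single probe passed, with 45378 of 388368 at unadjusted p under 0.05, above the 5% that chance gives on average. Under alternatives, 1 probe passed with a common median absolute deviation and 1 with a trended robust prior. With scan day as a fixed block the window count stayed at 0, with 3963 at unadjusted p under 0.05. Sham arrays were taken at 0 h and irradiated ones at 24 to 96 h, so time in culture goes with irradiation.

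Each line was also taken on its own. In GM12878 no window passed with limma (lowest adjusted p = 1.000), and 313 were at unadjusted p under 0.05, 204 of them higher. These 313 were 1.47% of the windows, under the 5% that chance gives. The count was 911 with loess, and it ran from 186 without the array at 48 h after 4 Gy to 637 without that at 24 h after 2 Gy. The lowest p was in the window of chromosome 8 from 90700001 to 90800000 (0.39, SE 0.11) among rises and of chromosome 11 from 14700001 to 14800000 (-0.49, SE 0.14) among falls. In IMR90, 5384 windows were at unadjusted p under 0.05, 414 of them higher and the others lower after irradiation. They were 25.3% of the windows, above the 5% that chance gives on average, but with correlated windows and 1 sham array this does not exclude chance. The count was 2457 without the IMR90 array at 24 h after 2 Gy. The lowest limma adjusted p was 0.0543. The window of chromosome 10 from 134300001 to 134400000 had the lowest p (-1.33, SE 0.17), followed among falls by chromosome 5 from 900001 to 1000000 (-1.06, SE 0.17) and chromosome 2 from 240200001 to 240300000 (-1.12, SE 0.18). Among rises, the window of chromosome 2 from 7800001 to 7900000 had the lowest p (0.54, SE 0.14, adjusted p = 0.0587). The difference of the irradiation effects between the lines passed in no window (lowest limma adjusted p = 0.218). There were 3769 windows at unadjusted p under 0.05, which is 17.7% and above the 5% that chance gives on average, with the same limit. Without IMR90 at 24 h after 2 Gy there were 1397. The lowest p was on chromosome 5 from 900001 to 1000000 (-1.17, SE 0.23).

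The IMR90 count lay at the edge of the threshold. It rose from 0 to 3347 windows with a trended robust variance prior, 2775 with scan day as a fixed block, 2699 without the dye term, 2457 with probes well above background on all arrays and 1345 with slide as a random block. It was 3247 without the GM12878 array at 24 h after 2 Gy, 1595 without the fractionated GM12878 array, 1275 without the IMR90 array at 48 h after 2 Gy, and 0 in each of the other 8 fits that left out 1 array. All these fits share the single IMR90 sham array.

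Chromosomes and chromosome ends showed where the IMR90 difference lay. On chromosome 19 the IMR90 sham array was at 0.92 and the irradiated arrays at 0.35 ± 0.14 (SD over 5 arrays), a difference of -0.57. Chromosome 22 differed by -0.52 (sham 0.84, irradiated 0.32 ± 0.10), chromosome 17 by -0.43 and chromosome 16 by -0.35, whereas chromosome 4 differed by -0.06, less than the SD of 0.08 between the irradiated arrays (-0.15 with a common median absolute deviation). Within 5 Mb of chromosome ends the sham was at 0.72 and the irradiated arrays at 0.25 ± 0.10 (-0.47). All 5 irradiated IMR90 arrays lay below the sham in 22 of the 23 classes. The 2 arrays at 2 Gy, which shared the sham's scan day and dyes, gave -0.58 on chromosome 19, -0.50 on chromosome 22 and -0.49 near chromosome ends, whereas chromosome 4 turned to 0.0013. With loess within arrays, the differences over all 5 arrays were smaller, -0.28 on chromosome 19 and -0.27 on chromosome 22. In GM12878 the same differences were -0.010 on chromosome 19, 0.0031 on chromosome 22 and 0.014 near chromosome ends, within the scatter of its irradiated arrays, and the arrays that shared the sham's day gave -0.11, -0.08 and -0.08. The exact permutation test over both lines called none of the 23 classes (lowest p = 0.0833, adjusted p = 0.426, two-sided), nor did the test of the difference between the lines (lowest p = 0.0556, adjusted p = 0.246). The smallest p that 36 choices allow is 0.0278, which cannot pass after adjustment unless most of the classes reach it.

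Dose was compared as 4 Gy against 2 Gy at matched times. No window passed (lowest limma adjusted p = 0.556), and 588 were at unadjusted p under 0.05, 199 of them higher after 4 Gy. These were 2.77% of the windows, under the 5% that chance gives, and the count turned on single arrays. Without 1 GM12878 array it was 98 (4 Gy at 24 h), 138 (2 Gy at 48 h), 178 (4 Gy at 48 h) or 2112 (2 Gy at 24 h), without 1 IMR90 array 320 (4 Gy at 48 h), 358 (4 Gy at 24 h) or 1217 (2 Gy at 24 h), and without either sham 1647. With loess within arrays 7 windows passed (2373 at unadjusted p under 0.05, above the 5%), and 1 with a trended robust prior; over all alternatives with every array or only the unexchanged ones, the unadjusted count ran from 250 to 3010. In IMR90 dose goes with dye and scan day, so the contrast rests mainly on GM12878. There the 2 Gy arrays had a slide and a scan day to themselves, and the 4 Gy arrays had a slide to themselves. With scan day as a fixed block, a fit in which the doses meet only through the sham arrays of different lines, no window passed, with 3010 at unadjusted p under 0.05. The lowest p was on chromosome 8 from 116500001 to 116600000 (-0.86, SE 0.11), where the GM12878 arrays were at -0.44 and -0.39 after 4 Gy and at 0.57 and 0.37 after 2 Gy, and the 4 single-dose IMR90 arrays between 0.43 and 0.52. Next came chromosome 8 from 93900001 to 94000000 (-0.96, SE 0.14) and chromosome 1 from 98100001 to 98200000 (-0.70, SE 0.11). Among windows higher after 4 Gy, the lowest p was on chromosome 3 from 64100001 to 64200000 (0.76, SE 0.13).

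Time was compared as 48 h against 24 h, within dose, dye and scan day. No window passed (limma adjusted p = 1.000 at the lowest), and 551 were at unadjusted p under 0.05, 532 of them higher at 48 h. These were 2.59% of the windows, under the 5% that chance gives, and the count was 21 with a common median absolute deviation and turned on single arrays. Without 1 GM12878 array it was 12 (2 Gy at 48 h), 19 (4 Gy at 24 h) or 151 (2 Gy at 24 h), without 1 IMR90 array 28 (4 Gy at 48 h), 1305 (2 Gy at 48 h) or 4353 (2 Gy at 24 h), and without either fractionated array 1127. The 3 with the lowest p lay in windows of low enrichment on chromosome 12 from 38600001 to 38700000 (0.54, SE 0.13), chromosome 6 from 96400001 to 96500000 (0.59, SE 0.15) and chromosome 13 from 57600001 to 57700000 (0.57, SE 0.15). The lowest p among falls was on chromosome 9 from 126300001 to 126400000 (-0.26, SE 0.10).

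Fractionation was compared as 4 fractions of 0.5 Gy, sampled at 96 h, against a single 2 Gy, which is the same summed dose but an earlier time. No window passed (lowest limma adjusted p = 0.932), with 687 at unadjusted p under 0.05, 149 of them higher after fractions. These were 3.23% of the windows, under the 5% that chance gives, and the count turned on single arrays. Without 1 GM12878 array it was 124 (2 Gy at 48 h), 1227 (2 Gy at 24 h) or 2155 (fractionated), without 1 IMR90 array 262 (fractionated) or 1937 (2 Gy at 24 h), and without either array of a treatment 240 (4 Gy at 24 h), 262 (4 Gy at 48 h) or 3172 (sham). With loess within arrays 5 windows passed (1677 at unadjusted p under 0.05, above the 5%), and 1346 were at unadjusted p under 0.05 with a common median absolute deviation. The unadjusted count fell with only the 9 unexchanged arrays, which leave 1 fractionated array. This contrast also goes with slide and scan day in both lines, and with scan day as a fixed block no window passed, with 1006 at unadjusted p under 0.05. The window of chromosome 4 from 91100001 to 91200000 had the lowest p among falls (-0.90, SE 0.16), followed by the chromosome 8 windows from 93900001 to 94000000 (-0.89, SE 0.16) and from 116500001 to 116600000 (-0.66, SE 0.12) also named for dose. Among rises it was the chromosome 3 window from 64100001 to 64200000 (0.75, SE 0.15). The dose and fractionation contrasts share the 2 Gy arrays, so part of this overlap may come from those arrays, which was not tested.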

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

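The tests on the IMR90 sham array, the input DNA and the scan day were chosen after the results were seen; the tests on chromosomes 14 and 2 were chosen after the scatter of the ratios was seen there, but before their input signal was looked at.

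The 6 arrays of each line were searched for a single array far from the others, by its gap to the nearest array over the whole range, compared with the 95% critical value of Dixon's test. Of 25 measures per line, 10 stood out in GM12878 and 3 in IMR90, where chance gives about 5%, and measures of one array are not independent. In GM12878 the array at 48 h after 2 Gy was the highest each time: on chromosome 2 the gap was 0.68 of the range, on chromosome 7 0.703, on chromosome 8 0.796, on chromosome 9 0.674, on chromosome 11 0.697, on chromosome 12 0.652, on chromosome 13 0.73, on chromosome 14 0.638, on chromosome 18 0.746 and on chromosome 21 0.702. In IMR90 the sham array was the highest each time: on chromosome 17 the gap was 0.63 of the range, on chromosome 22 0.643 and for the SD over probes 0.658 (1.19 against at most 0.89 on the other arrays).

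The IMR90 sham array had a steeper profile than all 5 irradiated IMR90 arrays. A single spread factor for the whole array accounts for part of it. With window means scaled to a common spread, the sham's mean near chromosome ends went from 0.72 to 0.63. The highest irradiated array (4 Gy at 24 h) went from 0.37 to 0.43. The sham still lay 0.20 above it, more than the SD of 0.12 between irradiated arrays, but this rests on 1 sham array. Scan day and dye do not account for the steeper profile. The irradiated arrays of the sham's own day and dyes lay 0.49 lower near chromosome ends (difference -0.49, SD between irradiated arrays 0.10). Irradiation stays open. In GM12878 the difference near chromosome ends was 0.014, with an SD of 0.13 between irradiated arrays. The irradiated GM12878 arrays of the sham's own scan day all lay below the sham there (0.34, 0.31 and 0.25 against 0.38). Those at 2 Gy, scanned on another day, lay above it (0.57 and 0.49). Whether an effect of irradiation would be specific to IMR90 therefore cannot be told, and there is 1 sham array per line. In its MeDIP channel the IMR90 sham was also the weakest array of its line, with a median spot intensity of 239. The 2 arrays of its day and dyes had 351.5 and 301, and the exchanged ones at least 596. Its derivative log-ratio SD, a measure of noise between neighbouring probes, was 0.79, against at most 0.58 on the irradiated IMR90 arrays. On GM12878 arrays it was 0.77 or more. Whether a weaker capture gave the steeper profile was not tested. The slide, capture efficiency and time in culture of the IMR90 sham also stay open, because it was alone on its slide and the only IMR90 array taken at 0 h. The GM12878 sham exceeded only the irradiated arrays of its own scan day, so whether an effect of time would be specific to IMR90 cannot be told either.

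The line difference covered 33.5% of the windows. The splits addressed chance among single arrays only. Of 100 splits of the 12 arrays into 6 and 6, 2 called as many windows (7113 for the real split and 7113 for the highest other). That other split is the same fit with the 3 dye-exchanged pairs turned. The split fits held no term for cell line, so the line difference added to the scatter of other splits and could hold their counts down. Chance is therefore not excluded by this comparison. Of all 462 splits only the real one keeps every scan day whole, so chance between days was not tested. Input DNA is excluded as the whole cause, since over the called windows the input differed against the direction of the call (-11.0% of the ratio difference), while the MeDIP channel alone differed by 0.81 in windows higher and -0.51 in windows lower in IMR90; in 316 of the called windows (4.44%), 251 of them lower in IMR90, the input did run with the call by 0.5 or more of the ratio difference, and in 11 of the 12 windows on chromosomes 14 and 2 below the GM12878 input was the lower one. Scan day cannot be told apart from cell line, because no day held both. With scan day as a random block 0 windows passed, as the sizes stayed (0.68 and -0.48) and the SE grew. In that fit the estimated correlation of arrays within a day was 0.91. No slide held both lines either, but the correlation within slides was 0.15, and 6042 windows passed with slide as a random block. The nesting alone therefore does not give the 0, and the day block decides nothing between day and cell line. The cell types themselves, which the design names, stay among the open explanations.

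GM12878 arrays scattered widely in most of 12 windows, taken as the longest run lower in IMR90 (chromosome 14 from 106200001 to 107300000) and the window of the largest fall (chromosome 2 from 89200001 to 89300000): their median SD was 0.63 there against 0.15 over all windows, although in 2 of the 12 it lay under that median. Lost copies in GM12878 are a candidate explanation: the input of GM12878 was lower than that of IMR90 by a median of -1.95 (SD of the difference over all windows 0.22), and 10 of the 12 windows lay in the lowest 1% of all windows. On the array at 48 h after 2 Gy the ratio exceeded that of the other GM12878 arrays by a median of 1.42, and its lower input signal (-0.56) made up 39.8% of the excess, too little to explain it alone and too much to set aside. A different mix of cells in that culture and weak signal in windows with little DNA stay open, and no biological explanation was tested for that array.

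For dose, chance could not be excluded: 11 of 35 splits of the 8 single-dose arrays gave as many windows at unadjusted p under 0.05 as 4 Gy against 2 Gy (995 in this fit, 4524 for the highest other split). For time, 12 of 35 splits gave as many as 48 h against 24 h (953, with 4524 for the highest other). That split, several times the real counts, put the GM12878 array at 48 h after 2 Gy on the side of 3 IMR90 arrays. The split of the GM12878 against the IMR90 arrays gave 3876. Cell line was a term of these fits, so this split counts how the single-dose arrays differ from the sham and fractionated ones between the lines. Those groups differ in dose and time too, so the split cannot tell array structure from dose and time. Among the 18 splits with 2 arrays of each line on each side, the highest was 2416, and 5 gave as many as dose and 6 as many as time. A split that kept each scan day whole, 2 Gy of GM12878 with 4 Gy of IMR90 against the rest, gave 2364.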

How the results depend on the processing

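Scan day blocks and the scaling of window means were chosen after seeing the data. With limma, irradiation in both lines, irradiation in GM12878 and 48 h against 24 h called 0 windows under every alternative run. Irradiation in 1 Mb windows did so too. The counts of these comparisons at unadjusted p under 0.05 moved by over 1.5 times. For 48 h against 24 h the count ran from 12 to 4353 when 1 array was left out. For both lines it ran from 1146 to 3963 over the alternatives with every array or only the unexchanged ones. Without the sham of 1 line, the fit for both lines gave the count of the other line alone. Of single probes, irradiation in both lines called 0, and 1 each with a common median absolute deviation and a trended robust prior. The regional classes also called 0 throughout, which says little, since their permutation test can hardly pass in this design. For the line difference, the count was 7113 and moved to 12252 without the dye term, 4091 with only the 9 unexchanged arrays, 10720 with window means scaled to a common spread and 0 with scan day as a random block; the cause was not tested, except that the 9-array fit has fewer arrays and the day block widened the SE and left the sizes. It ran from 3999 to 9633 when 1 array was left out. Of the 7113 windows, 96.7% were also called without the dye term, 97.2% with scaled window means and 57.3% with 9 arrays, all in the same direction. The share called in 1 Mb windows (27.7%) moved to 45.9% with loess, 47.5% with a common median absolute deviation, 55.4% without the dye term and 12.7% with 9 arrays, and ran from 17.0% to 40.8% when 1 array was left out.

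Irradiation in IMR90 called 0 windows, and 1 with normexp, 1 with loess, 2699 without the dye term, 2457 with probes well above background, 3347 with a trended robust prior, 1345 with slide as a random block and 2775 with scan day as a fixed block; it ran from 0 to 3247 when 1 array was left out. The interaction called 2 windows with a trended robust prior. For 4 Gy against 2 Gy, 7 windows passed with loess and 1 with a trended robust prior, and for fractionated against single 2 Gy 5 passed with loess. The difference between irradiated and sham IMR90 arrays on chromosome 19 (-0.57) kept its sign and was -0.28 with loess, -0.39 with normexp and -0.40 with a common median absolute deviation. The cause was not tested. Of 1601 values of named windows under alternatives, 1532 kept their direction and side of the threshold, 47 passed it newly, 20 no longer passed (all of the line difference, with scan day as a random block) and 2 reversed without the dye term: chromosome 10 from 49400001 for 4 Gy against 2 Gy (-0.0087) and chromosome 20 from 58800001 for fractionated against single 2 Gy (-0.11).

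The CpG trend, the narrower promoters and both gene list alternatives were not run, since no gene names or genome of this build were at hand. No paired analysis was possible because the groups hold 1 array each and share no replicate numbers; pairing by treatment and time is already part of the line difference. On every array 91.6% or more of the spots were well above background, and keeping only probes that were so on all arrays moved the number of windows called for irradiation in IMR90 and, at unadjusted p under 0.05, that for 48 h against 24 h (from 551 to 117).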

Other observations

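All values here were looked up after the results were seen. The fitted line difference and the fitted irradiation difference were correlated over different distances along the genome, which was not tested. The irradiation fit called no window and includes the single IMR90 sham array (irradiated minus sham -0.57 on chromosome 19). Its longer reach can therefore not be ascribed to irradiation. The fitted line difference of a window correlated with that of the next 100 kb window at r = 0.72, of the window 1000 kb away at 0.16 and of the window 5000 kb away at 0.04. The fitted irradiation difference in both lines correlated at 0.64, 0.42 and 0.23 over the same distances. These correlations are across windows, which are not independent.

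Some windows named for dose separated the GM12878 arrays into levels that follow neither scan day nor slide alone. The 2 Gy arrays and the 4 Gy arrays each had a slide to themselves, so these doses cannot be told apart from slide. The windows were also picked for their low p in the dose contrast. On chromosome 8 from 116500001 to 116600000, the GM12878 sham array was at 0.31 and the arrays after 2 Gy at 0.57 and 0.37, whereas those after 4 Gy were at -0.44 and -0.39 and the fractionated one at -0.19; the sham shared a scan day with the 4 Gy arrays and a slide with the fractionated one. On chromosome 3 from 64100001 to 64200000, the sham was at -0.13, the 2 Gy arrays at -0.26 and -0.23, the 4 Gy arrays at 0.53 and 0.67 and the fractionated array at 0.50. All 6 IMR90 arrays lay between 0.48 and 0.79 in that window.

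In GM12878, 87 windows had an input signal lower than in IMR90 by more than 0.5 on the log2 scale. Of these, 27 were called lower in IMR90 (31.0%, against 14.2% of all windows) and 20 higher (23.0%, against 19.3%). Whether these shares differ was not tested.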
